A study of Mus musculus with 39 samples.

How the data were processed

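Lung RNA was sequenced from 39 mice that lack Gprc5a, a receptor gene of airway and alveolar epithelium whose loss makes mice prone to lung adenocarcinoma. Of these, 20 carried the Gprc5a deletion alone (called KO here) and 19 also lacked Lcn2, which encodes lipocalin-2, a secreted protein that binds bacterial siderophores and carries iron (called DKO here). Each genotype was sampled at baseline at 8 weeks of age, and at 44 weeks of age, 7 months after NNK, a nitrosamine carcinogen of tobacco that was injected at 50 mg/kg 3 times a week for 8 weeks. The 4 groups held 10 KO baseline, 10 DKO baseline, 10 KO NNK and 9 DKO NNK libraries. Age and NNK changed together, and no unexposed mice of 44 weeks were analysed here, so a difference between NNK and baseline is that of both. The labels disagree on the tissue: the source field names lung tissue and another field names airway epithelium.

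Per the labels' protocols, total RNA was extracted with a column kit and 10 ng of it went into Ion AmpliSeq mouse transcriptome libraries, in which each gene is read from 1 short amplicon, so that counts do not scale with transcript length. Libraries were pooled 8 to a chip of the Ion Proton sequencer. Molecular identifiers are not given in the sources used here, so counts are of reads, and intervals and floors made from them cover counting error only. Reads were aligned and counted with STAR 2.7.0f and RSEM 1.3.1 on GRCm38, per the submitters' processing notes, which do not say which tool did which step. The parameters, the annotation behind the amplicons and the parts of Lcn2 and Gprc5a covered are not given in the sources used here. A sequence difference under a primer or an amplicon can stop a gene from being read at all. Because the counting's use of strand is not stated, overlapping genes and near-identical copies, such as histone genes, interferon-inducible p200 genes and immunoglobulin segments, can share reads and their values are uncertain.

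The deposited files, 1 per library, hold estimated counts, TPM and FPKM per gene as the authors' RSEM run gave them. The estimated counts as deposited were whole numbers (tolerance 1e-06) for 98.91% to 99.5% of a library's genes, those at 0 included, and were rounded to whole counts. The deposited TPM values served as an alternative, on the log2(TPM + 1) scale, and the FPKM values were not used. Each file lists 55573 gene identifiers, of which 55094 matched GENCODE M21 on GRCm38 with their version, 300 matched without it and 179 did not match, and 25970 had at least 1 count in some library. Total counts ran from 5845096 to 10985106 per library (median 7223974). No pair of libraries in a group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 10.46, so none was treated as a repeat deposit.

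Genes were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (robust fit, TMM scaling), with p adjusted by the Benjamini-Hochberg method over all genes tested and a threshold of 0.05. All 39 libraries entered 1 model with 4 group means, so that the comparisons share an estimate of the spread. The edgeR filter (filterByExpr, minimum count 10) left 14825 genes. The 5 contrasts were DKO against KO at baseline and after NNK, NNK against baseline in KO and in DKO, and the difference of the latter pair, called the interaction. CPM are counts per 1e+06 of the TMM-scaled library size, and log2 CPM used a prior count of 2. Adjusted p-values in the text are from this test unless another is named. Lcn2 was also compared on log2(CPM + 1) by 2-sided permutation tests, exact where a group held fewer than 10 libraries and otherwise with 100000 resamples (Python 3.11.15, scipy 1.17.1). Where a group had 0 counts of a gene, its fold is given as a bound from 3 counts over the group. Where it had 1 to 3 counts, the ratio of CPM is given with its 95% exact binomial interval, and fitted log2 values of such genes depend on the prior count.

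Gene lists were fixed before the data were examined: 23 of lung, immune and other cell types and 20 of pathways and controls. Each was tested with camera of limma 3.58.1, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and adjusted over the lists of a comparison. Thymocytes had 4 tested members, under the minimum of 5, and the other 42 lists were tested. For each list the text gives how many members passed over all genes tested, how many passed when p was adjusted over the list alone, and the adjusted p of camera with a correlation estimated from the residuals. Fry, which asks only whether a list's genes move one way on balance, was an alternative. A list's level in a library is the mean of its members' log2 CPM less the mean of the library's code block.

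The genes named were set by a rule fixed together with the lists. Lcn2 and Gprc5a were always named. Among genes past the threshold with a mean of at least 1 CPM and an established symbol, the 8 largest log2 changes in each direction were named if at least 80% of the libraries of the first group lay beyond the median of the second (not required for the interaction). For each list past the threshold, up to 3 members with the smallest p that passed in the direction of the list were named. Only part of the genes that the rule names are described, and results of some are not reported here. The same rule was run again, after the data were seen, without the genes that behave as on or off, defined next.

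The labels give no batch. The library codes split into codes up to 11 (23 libraries, code block 1) and from 12 (16 libraries, code block 2), and each group has libraries in both blocks: 6 and 4 in each of the first 3 groups and 5 and 4 in DKO NNK. The first principal component of the log2 CPM held 58.4% of the variance and followed the code block (R² 0.979), and components 3 and 4, with 5.5% and 4%, followed the group (R² 0.841 and 0.815). Block 1 libraries had 15660 to 16654 genes with a count and block 2 libraries 17386 to 18442. The groups are balanced over the blocks and the model had no block term, which leaves the block in the spread. Fits with the block, the F or M that opens each title, and both were alternatives set beforehand. Fits within each block were added after the data were seen. The letter's meaning is not stated in the labels (20 F, 19 M). Also after the data were seen, 175 genes were found whose libraries within a block fell into a high and a low set, at least 2 log2 units apart on log2(CPM + 0.5) with at least 2 libraries on each side, called on/off genes here. A full difference between groups also meets this, and Lcn2 is among the 175.

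Other alternatives set beforehand were DESeq2 size factors and the DESeq2 1.42.0 Wald test, limma-voom, limma-trend on log2(TPM + 1), no filter, a filter of 5 CPM in 9 libraries, surrogate variables from sva 3.50.0, only the groups compared, a prior count of 0.5 for the lists, estimated list correlations, fry, and leaving out each library. The tests were checked on counts simulated from the real means, dispersions and library sizes with 200 changed genes. Of 50 genes changed 4-fold, 78% were called by genotype at baseline, 80% after NNK, 86% for NNK in KO, 72% in DKO and 78% for the interaction. At 1.5-fold the shares were 12%, 18%, 12%, 8% and 2%, and at 2-fold 48%, 46%, 40%, 52% and 32%. There were 0 or 1 false calls per comparison, and with the block as a term 6 to 11. A simulated list shifted by 1 log2 unit was called in each, with 0 to 2 other lists. Simulated genes were independent, leaving out correlation in real lists and sample structure. Other splits of the real libraries called up to 2928 genes.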

Results

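Each of the 39 libraries came from 1 mouse. Total counts ran from 5845096 to 10985106 in the 10 KO baseline libraries and from 5982112 to 8621917 in the 10 DKO baseline libraries. After NNK they ran from 5960723 to 10337118 in 10 KO libraries and from 6189297 to 7815120 in 9 DKO libraries. The 10 genes with the most counts took 11.28% to 26.15% of a library.

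Lcn2 (ENSMUSG00000026822.14, GRCm38 chromosome 2, 32384633 to 32388252) was read first, because its deletion separates the genotypes. KO libraries held 520 to 1320 Lcn2 counts at baseline (108 ± 33.8 CPM, mean ± SD, n = 10) and 1133 to 5151 after NNK (387 ± 200 CPM, n = 10). DKO libraries held 0 to 5 counts at baseline (0.266 ± 0.292 CPM, n = 10) and 0 to 12 after NNK (0.569 ± 0.697 CPM, n = 9). On the log2(CPM + 1) scale the genotypes differed by −6.39 at baseline (permutation p = 2e-05, the smallest that the resamples can give; adjusted over 4 tests 4.34e-05; −6.41 and −6.37 in blocks 1 and 2). After NNK they differed by −7.85 (exact permutation p = 2.17e-05, adjusted p = 4.34e-05; −7.98 and −7.73 in the blocks). Lcn2 itself rose with NNK in KO lungs by 1.70 (permutation p = 0.0001, adjusted p = 0.000133; 1.71 and 1.68 in the blocks), with 9 of 10 libraries above the baseline median, and the edgeR fold was 3.57 (log2 1.83 ± 0.371 SE, adjusted p = 0.00174). In DKO lungs the difference was 0.24 (exact permutation p = 0.267), and no fold is given because both groups lie near the floor. Gprc5a had 0 to 2 counts per library and 4 in all, as both genotypes lack it. Each library had the Lcn2 level of its labelled genotype, as far as the amplicon lies in the deleted part.

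**Figure D1:**
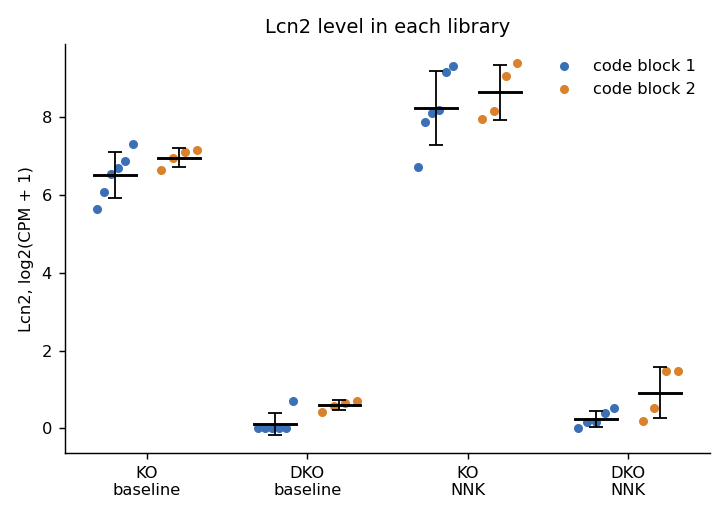
Lcn2 as log2(CPM + 1) in each of the 39 libraries, by group and code block. Points are libraries and black lines the mean and SD of a group within a block; KO groups average 108 and 387 CPM and DKO groups 0.266 and 0.569 CPM.

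Genes of other tissues separated libraries inside each group. These 7 genes were chosen after their values were seen. In 13 of the 16 block 2 libraries the squamous epithelial genes Krt4, Krt13 and Lor ran from 549 to 4000, from 231 to 2160 and from 264 to 2050 CPM, and Krt14 from 7.21 to 66.7 CPM. In the same libraries the fast skeletal muscle genes Acta1, Mylpf and Myh1 ran from 80.4 to 738, from 87.5 to 744 and from 40 to 422 CPM. The other 3, KO baseline 7, DKO baseline 7 and DKO NNK 6, had 4.42 to 13.2 CPM of Krt4 and 2.27 to 8.68 CPM of Acta1. Block 1 libraries had 0 to 1.64 CPM of Krt4 and 0 to 0.595 CPM of Lor, while Acta1 ran from 0.407 to 1340 CPM, with the highest value in KO baseline 4. Of the 1407 olfactory receptor genes, block 2 libraries read 61.8% to 69.4% and block 1 libraries 4.98% to 11.7%. In KO NNK 7, a library with title letter F, Xist stood at 390 CPM against 716 to 1080 CPM in the other 7 block 2 libraries with that letter, and the Y-linked Ddx3y at 23.7 CPM against 31.9 to 69.2 CPM in the 8 with letter M.

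**Figure D2:**
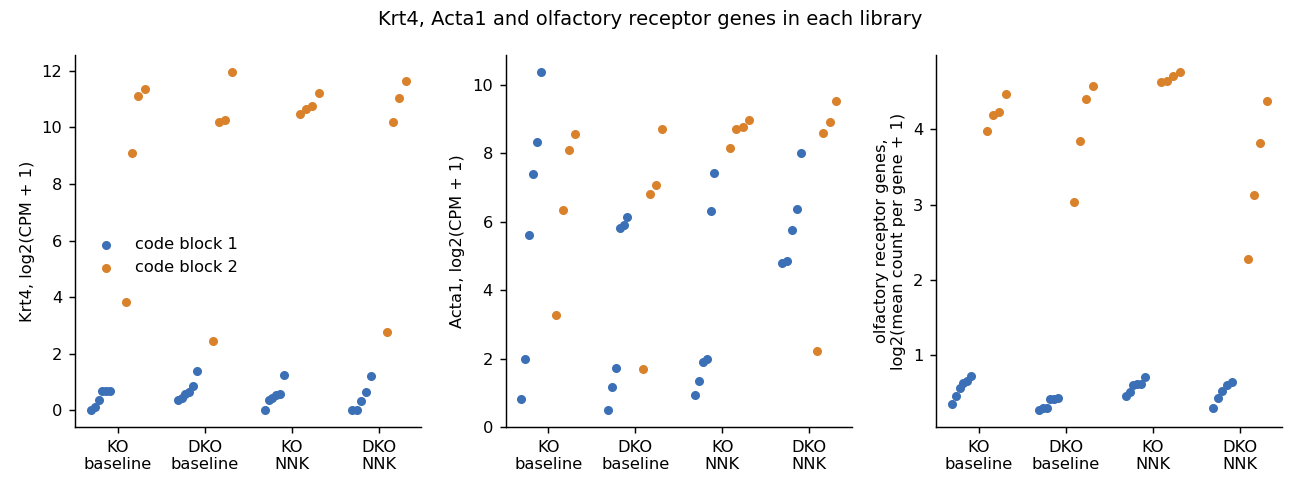
Krt4 and Acta1 as log2(CPM + 1), and the mean count of the olfactory receptor genes as log2(count + 1), by group and code block. Points are libraries; Krt4 lies between 549 and 4000 CPM in 13 block 2 libraries and at most at 1.64 CPM in block 1.

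**Figure D3:**
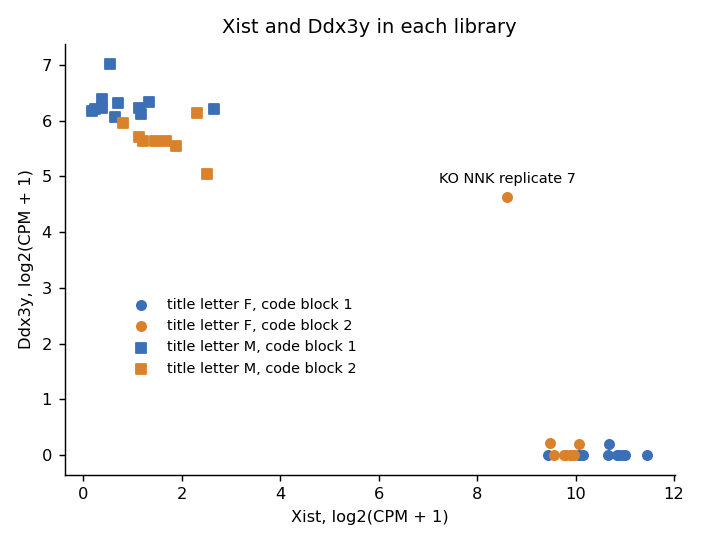
Xist against Ddx3y, both as log2(CPM + 1), in each library, with title letter as the symbol and code block as the colour. KO NNK 7 lies apart from both letters, at 390 CPM of Xist and 23.7 CPM of Ddx3y.

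DKO against KO lungs at baseline compared genotypes, which may also differ in strain background, before exposure. Besides Lcn2 (log2 −8.57 ± 0.553 SE, adjusted p = 3.46e-14), the aspartic protease gene Ctse was 11.5-fold lower in DKO lungs, at 2.12 ± 1.14 against 24.7 ± 11.8 CPM (n = 10 each, adjusted p = 7.61e-06, lower in 10 of 10 libraries). Csf2rb2, which encodes a beta chain of the interleukin-3 receptor, was 10.1-fold lower (3.96 ± 1.46 against 39.9 ± 24.3 CPM, adjusted p = 7.61e-06). The adhesion receptor gene Adgra3 was 4.37-fold higher (60.9 ± 19.7 against 13.9 ± 11 CPM, adjusted p = 0.000492), and the uroplakin gene Upk2 4.28-fold higher (16.3 ± 10 against 3.79 ± 1.67 CPM, adjusted p = 0.00592). Within blocks 1 and 2 the log2 differences were −3.29 and −3.80 for Ctse, −2.69 and −3.84 for Csf2rb2, 2.10 and 2.16 for Adgra3 and 2.26 and 1.57 for Upk2. Hs3st1, a heparan sulfate sulfotransferase gene, was 11.7-fold higher (adjusted p = 0.00178).

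Other genes called were on/off, a state a large group difference can itself give, as with Lcn2. Odc1, the rate-limiting enzyme of polyamine synthesis (chromosome 12, 17544794 to 17551505), stood at 98.7 ± 17.6 against 0.973 ± 0.848 CPM (log2 6.65 ± 0.697 SE, adjusted p = 2.62e-08, 7.23 and 6.08 in the blocks). On chromosome 10, Lta4h, which makes leukotriene B4 (93453411 to 93484875), stood at 93.5 ± 69.4 against 1.23 ± 1.07 CPM, the ETS factor gene Elk3 (93247414 to 93311135) at 73.7 ± 43 against 1.84 ± 0.549 CPM and Vezt (93939165 to 94035817) at 6.38 ± 4.11 against 0.121 ± 0.157 CPM (adjusted p = 2.89e-05, 7.61e-06 and 0.000623). Riok2, a kinase gene of ribosome maturation, stood at 33.8 ± 5.21 against 1.74 ± 5.03 CPM (adjusted p = 0.00054). Vps13b, a lipid transfer protein gene (chromosome 15, 35371160 to 35931229), stood at 0.324 ± 0.232 against 72.7 ± 18.7 CPM (log2 −7.78 ± 0.348 SE, adjusted p = 2.59e-19, −8.31 and −7.26 in the blocks). The ribonucleotide reductase gene Rrm2 had 0 counts in KO and was at least 295-fold higher in DKO lungs, and Ttc39aos1, at 0 in DKO, at least 105-fold lower (adjusted p = 1.8e-05 and 2.43e-08). The synaptonemal complex gene Sycp1 had a count ratio of KO to DKO of 2460 (95% counting interval 442 to 97300, adjusted p = 0.00155). The neuropeptide gene Npy was 43.5-fold higher (adjusted p = 0.0156, and 0.0586 without DKO baseline 8). Outside the on/off genes, the fast myosin gene Myh2 stood at 0.11 ± 0.195 against 15.7 ± 32.9 CPM (adjusted p = 0.0151, 0.0956 without KO baseline 4, the library with the most Acta1, and log2 −2.28 in block 2).

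Of the gene lists, 5 passed. Parentheses give the adjusted p over all libraries and in blocks 1 and 2 alone, with "reversed" for the opposite direction. The interferon response list was higher in DKO lungs, with 21 of 23 members above 0, a median log2 of 0.37 and 7 of 10 libraries above the KO median (adjusted p = 0.000106, blocks 0.0211 and 2.99e-05). The ciliated cell list was higher, with 15 of 17 above 0 and a median of 0.37 (7 of 10 libraries; adjusted p = 0.000721, blocks 7.88e-05 and 0.705). Antigen presentation by MHC class II was higher, with a median of 0.49 over 12 genes (10 of 10 libraries; adjusted p = 0.00981, blocks 0.199 and 4.75e-06). Neutrophil markers were lower, with a median of −0.69 over 15 genes (7 of 10 libraries; adjusted p = 0.00981, blocks 0.00726 and 0.217), and xenobiotic enzymes higher, with a median of 0.15 over 28 genes (6 of 10 libraries; adjusted p = 0.0476, blocks 0.0233 and 0.612). With an estimated correlation the adjusted p = 0.838 for each of the 5. Over all genes tested 0 members of these lists passed (edgeR), with 2 interferon, 3 ciliated, 0 MHC class II, 1 neutrophil and 2 xenobiotic genes at an unadjusted p under 0.05 in the list's direction. Adjusted over the list alone, 1 neutrophil gene fell and 0 passed in the other 4. Skeletal muscle genes were not past the threshold (adjusted p = 0.0733). In all 79 of 14825 genes passed, 35 higher and 44 lower, and 950 had an unadjusted p under 0.05. Of the 79, 22 were on/off genes and 77 had the same sign in both blocks. The model with title letter and block called 181 (74 higher, 107 lower), block 1 alone 57 and block 2 alone 82.

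DKO against KO lungs after NNK compared these genotypes, with that limit, in exposed animals. The lists of ciliated cells, dividing cells, B cells and plasma cells were lower in DKO lungs, and those of alveolar type 1 and type 2 cells, endothelium and immediate early genes higher, by camera with its preset correlation. With an estimated one 0 of the 11 lists called so held (adjusted p = 0.201 to 0.685, 6 of 42 lists at an unadjusted p under 0.05), and in block 2 alone the ciliated list was reversed (adjusted p = 0.0458). The ciliary dynein gene Dnah5 was 2.38-fold lower (26.3 ± 11.3 against 62.7 ± 35.4 CPM, n = 9 and 10, adjusted p = 0.03, lower in 9 of 9 libraries), with log2 differences of −1.79 and −0.14 in blocks 1 and 2. The B cell coactivator gene Pou2af1 was 3.58-fold lower (23.1 ± 14.4 against 82.6 ± 90.8 CPM, adjusted p = 0.03) and the mitotic kinase gene Aurka 2.23-fold lower (3.55 ± 0.95 against 7.93 ± 4.92 CPM, adjusted p = 0.03). The MAPK phosphatase gene Dusp1 was 2.02-fold higher (368 ± 228 against 182 ± 69 CPM, adjusted p = 0.0387; DKO NNK 6 at 957 CPM), and the gastrin-releasing peptide gene Grp, a product of pulmonary neuroendocrine cells, 5.26-fold higher (25.7 ± 10.3 against 4.87 ± 4.72 CPM, adjusted p = 0.000985). In the blocks the log2 differences were −1.89 and −1.56 for Pou2af1, −0.67 and −1.68 for Aurka, 0.98 and 1.02 for Dusp1 and 2.65 and 2.20 for Grp.

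Dcstamp, which takes part in macrophage fusion, was 9.48-fold higher (11.5 ± 5.68 against 1.2 ± 1.06 CPM, adjusted p = 2.51e-05). Lrp10, a receptor gene of the low-density lipoprotein family (chromosome 14, 54464137 to 54471497), was 13.7-fold lower (6.9 ± 4.17 against 94.5 ± 16.3 CPM, adjusted p = 1.51e-06).

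On/off genes were called too. Naip6, a NOD-like receptor gene (chromosome 13, 100281121 to 100317674), stood at 28.3 ± 7.46 against 0.0571 ± 0.142 CPM (log2 8.69 ± 0.431 SE, adjusted p = 4.75e-18, 10.81 and 7.55 in the blocks) and the p53 target Phlda3 (chromosome 1, 135766119 to 135769136) at 42 ± 23 against 0.431 ± 0.309 CPM (adjusted p = 2.28e-08). Catspere1 had 0 counts in KO and was at least 243-fold higher in DKO lungs (adjusted p = 0.00048), as was, by at least 37.9-fold, the ephrin receptor gene Ephb1, which is not an on/off gene (adjusted p = 1.49e-06). Vps13b was 271-fold lower (adjusted p = 2.99e-19, log2 −8.21 and −7.69 in the blocks). Sycp1 and the cartilage protein gene Cilp had 0 counts in DKO and were at least 1080-fold and 134-fold lower (adjusted p = 0.000535 and 9.55e-07). On chromosome 1, Ifi213 (173566283 to 173599274) and the NK receptor gene Cd244a (171559193 to 171609746) had count ratios of KO to DKO of 958 (172 to 37900) and 363 (124 to 1760), with adjusted p of 3.37e-07 and 2.88e-07.

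Ciliated cell markers had a median log2 of −0.74 (9 of 9 libraries beyond the other group's median, adjusted p = 1.76e-09, blocks 4.2e-16 and 0.0458 reversed, p = 0.337 with estimated correlation). Of 17 genes 1 fell and 16 did not pass, 11 fell adjusted over the list alone. Cell cycle genes had a median of −0.68 (6 of 9 libraries, adjusted p = 2.35e-05, blocks 0.0172 and 0.00087, p = 0.521 with estimated correlation). Of 25 genes 1 fell and 24 did not pass, 8 fell adjusted over the list alone. B cell markers had a median of −0.89 (8 of 9 libraries, adjusted p = 0.000205, blocks 0.198 and 7.45e-05, p = 0.685 with estimated correlation). Of 15 genes 1 fell and 14 did not pass, 2 fell adjusted over the list alone. Plasma cell markers had a median of −0.62 (9 of 9 libraries, adjusted p = 0.000786, blocks 0.00376 and 0.224, p = 0.337 with estimated correlation). Of 12 genes 0 passed in edgeR (5 lower at unadjusted p under 0.05), 4 fell adjusted over the list alone. Adipocyte markers had a median of −1.59 (8 of 9 libraries, adjusted p = 0.0391, blocks 0.198 and 0.0583, p = 0.685 with estimated correlation). Of 9 genes 0 passed in edgeR (3 lower at unadjusted p under 0.05), 1 fell adjusted over the list alone. Libraries of block 2 with high Krt4 and Acta1 numbered 4 of 4 in KO and 3 of 4 in DKO lungs after NNK.

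Immediate early and heat shock genes had a median of 0.82 (8 of 9 libraries, adjusted p = 1.84e-06, blocks 0.00105 and 0.000498, p = 0.337 with estimated correlation). Of 20 genes 1 rose and 19 did not pass, 12 rose adjusted over the list alone. Endothelial markers had a median of 0.39 (9 of 9 libraries, adjusted p = 2.76e-05, blocks 0.000344 and 0.00162, p = 0.337 with estimated correlation). Of 15 genes 0 passed in edgeR (4 higher at unadjusted p under 0.05), 3 rose adjusted over the list alone. Alveolar type 2 markers had a median of 0.42 (9 of 9 libraries, adjusted p = 0.000214, blocks 0.0013 and 0.0627, p = 0.521 with estimated correlation). Of 14 genes 0 passed in edgeR (3 higher and 1 lower at unadjusted p under 0.05), 3 rose adjusted over the list alone. Alveolar type 1 markers had a median of 0.46 (9 of 9 libraries, adjusted p = 0.00034, blocks 2.64e-05 and 0.106, p = 0.337 with estimated correlation). Of 11 genes 0 passed in edgeR (2 higher at unadjusted p under 0.05), 1 rose adjusted over the list alone. MAPK output genes had a median of 0.22 (8 of 9 libraries, adjusted p = 0.0093, blocks 0.00508 and 0.337, p = 0.521 with estimated correlation). Of 15 genes 0 passed in edgeR (4 higher at unadjusted p under 0.05), 1 rose adjusted over the list alone. Without DKO NNK 2 the MAPK list had an adjusted p of 0.0764. Of the p53 targets 1 rose and 20 did not pass, 4 rose adjusted over the list alone (adjusted p = 0.0093, blocks 0.0521 and 0.0686, p = 0.201 with estimated correlation). Their median log2 was 0.07 and the mean 0.46, the gene that rose was Phlda3, and the adjusted p was 0.0685 without on/off genes.

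In all 264 genes passed, 113 higher and 151 lower, and 1958 had an unadjusted p under 0.05. Limma-trend on log2(TPM + 1) gave the opposite split, with 210 higher and 134 lower of 344. Of the 264, 46 were on/off genes and 258 had the same sign in both blocks. The model with letter and block called 1355 (528 higher, 827 lower), block 1 alone 603 (196 and 407) and block 2 alone 526 (339 and 187). At both times 13 genes were higher in DKO lungs, where 0.267 would be shared by independent lists, and 23 were lower, where 0.448 would be.

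NNK against baseline in KO lungs compared mice of 44 weeks, 7 months after NNK, with mice of 8 weeks, so exposure and age changed together. By camera with its preset correlation, the lists of cytokines and chemokines, cell cycle, plasma cells, T cells, antigen presentation and checkpoints were higher after NNK, and those of endothelium, matrix and alveolar type 1 cells lower. With an estimated one 0 of the 18 lists called so held (adjusted p = 0.0607 to 0.518, 8 of 42 lists at an unadjusted p under 0.05). The T cell attractant Cxcl9, an on/off gene, rose 15.3-fold (69.7 ± 77 against 4.57 ± 2.58 CPM, n = 10 each, adjusted p = 6.03e-05, 9 of 10 libraries) and the chemokine gene Ccl20 19.6-fold (10.1 ± 15.1 against 0.487 ± 0.373 CPM, adjusted p = 0.000156). Spp1, which encodes osteopontin, rose 6.16-fold (258 ± 161 against 41.8 ± 24.1 CPM, adjusted p = 0.00152), and Jchain, the joining chain of secreted immunoglobulins, 6.37-fold (839 ± 576 against 132 ± 151 CPM, adjusted p = 0.00112). The collagen gene Col1a1 fell 2.94-fold (274 ± 63.5 against 807 ± 358 CPM, adjusted p = 1.89e-05) and the angiopoietin receptor gene Tek 2.61-fold (57.9 ± 26.3 against 151 ± 61.1 CPM, adjusted p = 0.00174). In blocks 1 and 2 the log2 changes were 4.12 and 3.65 for Cxcl9, 4.38 and 3.84 for Ccl20, 2.50 and 2.69 for Spp1, 2.31 and 3.47 for Jchain, −1.31 and −1.83 for Col1a1 and −1.62 and −1.22 for Tek.

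The largest rises outside on/off genes were in Glycam1, a mucin-like ligand of L-selectin made by high endothelial venules (18.8 ± 17.1 against 0.181 ± 0.236 CPM, adjusted p = 1.37e-05), the fibrinogen gene Fga (39.2-fold, adjusted p = 7.07e-05) and the albumin gene Alb (20.2 ± 55.9 against 0.568 ± 0.361 CPM, adjusted p = 0.00128). KO NNK 6 had 179 CPM of Alb, and without it the adjusted p was 0.0717 (log2 1.72 in block 2). The chemerin receptor gene Ccrl2 fell 6.19-fold (adjusted p = 3.71e-06) and Ctse 4.59-fold (adjusted p = 0.00179). Among on/off genes, Odc1 stood at 53.5 ± 49.6 against 0.973 ± 0.848 CPM (adjusted p = 3.13e-07). Dmbt1, a mucosal scavenger receptor gene, had a count ratio of 156 (42.7 to 1290, adjusted p = 4.57e-05). Naip6, Tfcp2l1, Cox7a2, Acy1, Phlda3 and Cops8 fell 80.5-fold to 443-fold, with Phlda3 at 0.431 ± 0.309 against 56.3 ± 17.7 CPM and the 6 adjusted p from 5.47e-18 to 5.04e-07. Ephb1, not an on/off gene and at 0 after NNK, was at least 76.9-fold lower (adjusted p = 3.08e-07).

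Cytokine and chemokine genes had a median log2 of 1.74 (10 of 10 libraries beyond the other group's median, adjusted p = 1.1e-09, blocks 0.00015 and 0.000116, p = 0.0607 with estimated correlation). Of 17 genes 9 rose and 8 did not pass, 11 rose adjusted over the list alone. Cxcl10 rose 5.49-fold (adjusted p = 0.00285). Cell cycle genes had a median of 0.88 (10 of 10 libraries, adjusted p = 6.08e-10, blocks 4.96e-05 and 2.53e-05, p = 0.181 with estimated correlation). Of 25 genes 7 rose and 18 did not pass, 15 rose adjusted over the list alone. Mcm6, a helicase subunit gene, rose 2.04-fold (adjusted p = 0.00152), the kinetochore motor gene Cenpe 2.15-fold (adjusted p = 0.00368), and the on/off gene Rrm2, at 0 at baseline, at least 381-fold (adjusted p = 5.75e-06, 7 of 10 libraries). Plasma cell markers had a median of 0.79 (10 of 10 libraries, adjusted p = 8.39e-06, blocks 0.000614 and 0.00225, p = 0.0706 with estimated correlation). KO baseline 4 stood apart at 0.61 (others −0.84 to −0.08). Of 12 genes 4 rose and 8 did not pass, 5 rose adjusted over the list alone. Besides Jchain, Igkc rose 8.07-fold (adjusted p = 0.0162, log2 1.85 in block 1) and Mzb1, an on/off gene with baseline libraries on both sides of its gap, 28.4-fold (adjusted p = 0.0126, and 0.0513 without KO NNK 2). B cell markers had a median of 1.06 (8 of 10 libraries, adjusted p = 0.00251, blocks 0.15 and 0.00288, p = 0.518 with estimated correlation). Of 15 genes 1 rose and 14 did not pass, 10 rose adjusted over the list alone, and the complement receptor gene Cr2 rose 3.6-fold (adjusted p = 0.0121). T cell markers had a median of 1.49 (7 of 10 libraries, adjusted p = 8.06e-05, blocks 0.213 and 0.000259, p = 0.494 with estimated correlation). Of 18 genes 8 rose, 1 fell and 9 did not pass, 15 rose and 1 fell adjusted over the list alone. Zap70 rose 2.26-fold (adjusted p = 0.00216), Ctla4 3.98-fold (adjusted p = 0.00525) and Cd4 4.39-fold (adjusted p = 0.0125, 0.0796 without KO NNK 10, and log2 0.97 in block 1).

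Immune checkpoint genes had a median of 0.92 (8 of 10 libraries, adjusted p = 4.93e-05, blocks 0.000614 and 0.0524, p = 0.181 with estimated correlation). Of 14 genes 8 rose, 1 fell and 5 did not pass, 9 rose and 2 fell adjusted over the list alone. Pdcd1, which encodes PD-1, rose 5.1-fold (adjusted p = 3.73e-05) and Tnfrsf9 3.84-fold (adjusted p = 0.000264); the one that fell, Cd276, an on/off gene named after its values were seen, had a log2 change of −3.09 (adjusted p = 0.0189). MHC class I genes had a median of 0.56 (9 of 10 libraries, adjusted p = 0.000433, blocks 0.00544 and 0.00749, p = 0.244 with estimated correlation). Of 14 genes 4 rose and 10 did not pass, 5 rose adjusted over the list alone. The transporter gene Tap1 rose 2.58-fold (adjusted p = 0.00364), the transactivator gene Nlrc5 2.26-fold (adjusted p = 0.00572) and Psmb9 1.88-fold (adjusted p = 0.0336, log2 0.38 in block 2). MHC class II genes had a median of 0.91 (9 of 10 libraries, adjusted p = 0.000493, blocks 0.00458 and 0.0023, p = 0.282 with estimated correlation). KO NNK 1 stood apart at −2.96 (others −0.19 to 1.52). Of 12 genes 2 rose and 10 did not pass, 8 rose adjusted over the list alone, with Ciita 2.19-fold (adjusted p = 0.0102) and Ctss 1.93-fold (adjusted p = 0.0331, 0.0523 to 0.0905 without any 1 of 8 libraries, and log2 0.23 in block 2) higher. Interstitial macrophage and monocyte markers had a median of 0.50 (10 of 10 libraries, adjusted p = 0.0123, blocks 0.0962 and 0.0336, p = 0.181 with estimated correlation). Of 13 genes 2 rose and 11 did not pass, 6 rose adjusted over the list alone, with Apoe 1.53-fold (adjusted p = 0.0184) and Trem2 3.05-fold (adjusted p = 0.0294, 0.0528 to 0.246 without any 1 of 5 libraries, and log2 0.36 in block 2) higher.

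Acute phase and epithelial defence genes had a median of 0.82 (10 of 10 libraries, adjusted p = 8.39e-06, blocks 4.39e-06 and 0.0336, p = 0.0873 with estimated correlation). KO NNK 1 stood apart, with a list level of 2.13 (others 0.08 to 0.83), as did KO baseline 3, with 0.88 (others −1.07 to −0.11). Of 20 genes 4 rose and 16 did not pass, 5 rose adjusted over the list alone. Retnla rose 4.15-fold (1770 ± 1320 against 426 ± 291 CPM, adjusted p = 0.00513, log2 0.96 in block 2), the chitinase-like gene Chil1 1.9-fold (adjusted p = 0.0268, log2 0.41 in block 2) and the mucin gene Muc4 2.15-fold (adjusted p = 0.026, 0.0915 without KO NNK 1, and log2 −0.17 in block 2). Lung tumour and damaged alveolar epithelium genes had a median of 0.56 (10 of 10 libraries, adjusted p = 0.000435, blocks 0.00223 and 0.116, p = 0.146 with estimated correlation). Of 20 genes 4 rose and 16 did not pass, 7 rose and 1 fell adjusted over the list alone. Besides Spp1, Cd24a rose 2.14-fold (adjusted p = 0.000264; KO NNK 1 at 1020 CPM) and Clu 2.35-fold (adjusted p = 0.00096). Ciliated cell markers had a median of 0.56 (7 of 10 libraries, adjusted p = 0.00044, blocks 1.07e-06 and 0.473 reversed, p = 0.496 with estimated correlation). Of 17 genes 0 passed in edgeR (8 higher at unadjusted p under 0.05), 3 rose adjusted over the list alone. Adipocyte markers had a median of 0.89 (8 of 10 libraries, adjusted p = 0.0247, blocks 0.126 and 0.0948, p = 0.518 with estimated correlation). Of 9 genes 2 rose and 7 did not pass, 2 rose adjusted over the list alone.

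Endothelial markers had a median of −0.69 (10 of 10 libraries, adjusted p = 2.28e-08, blocks 2.08e-05 and 2.06e-06, p = 0.0873 with estimated correlation). Of 15 genes 6 fell and 9 did not pass, 8 fell adjusted over the list alone. Besides Tek, the tight junction gene Cldn5 fell 2.16-fold (adjusted p = 0.00281) and the VEGF receptor gene Kdr 1.6-fold (adjusted p = 0.00797). Matrix genes had a median of −0.63 (10 of 10 libraries, adjusted p = 6.82e-06, blocks 0.000105 and 0.00298, p = 0.25 with estimated correlation). Of 26 genes 1 rose, 6 fell and 19 did not pass, 2 rose and 15 fell adjusted over the list alone. Fibrillin Fbn1 fell 2.15-fold (adjusted p = 7.26e-05) and elastin Eln 2.96-fold (adjusted p = 0.0163), and the one that rose was the macrophage elastase gene Mmp12, named after its values were seen (22.2 ± 29.4 against 5.56 ± 2.6 CPM, adjusted p = 0.0152). Alveolar type 1 markers had a median of −0.42 (10 of 10 libraries, adjusted p = 0.00388, blocks 0.0805 and 0.00046, p = 0.388 with estimated correlation). Of 11 genes 3 fell and 8 did not pass, 3 fell adjusted over the list alone, with Rtkn2 1.8-fold, Spock2 1.88-fold and Akap5 1.92-fold lower (adjusted p = 0.0153, 0.0304 and 0.0322; Rtkn2 log2 −0.46 in block 2). Fibroblast markers had a median of −0.60 (8 of 10 libraries, adjusted p = 0.00405, blocks 0.0024 and 0.162, p = 0.494 with estimated correlation). Of 13 genes 1 fell and 12 did not pass, 1 rose and 5 fell adjusted over the list alone, with Fbln1 1.63-fold lower (adjusted p = 0.0305), and without KO NNK 4 the list had an adjusted p of 0.0552. Immediate early genes had a median of −0.39 (8 of 10 libraries, adjusted p = 0.0305, blocks 0.016 and 0.566, p = 0.518 with estimated correlation). Of 20 genes 1 fell and 19 did not pass, 1 fell adjusted over the list alone, with Dusp1 1.86-fold lower (adjusted p = 0.0337).

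In all 839 genes passed, 427 higher and 412 lower, and 2508 had an unadjusted p under 0.05. Limma-trend on log2(TPM + 1) called 684, with 259 higher and 425 lower. Of the 839, 38 were on/off genes and 825 had the same sign in both blocks. The model with letter and block called 2106 (1095 higher, 1011 lower), of which 833 were among the 839, block 1 alone called 773 and block 2 alone 2968 (1292 and 1676).

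Over the same interval in DKO lungs the lists of cytokines, checkpoints, MAPK output and alveolar type 2 cells were higher, and those of ciliated cells, club cells and smooth muscle lower, by camera with its preset correlation. With an estimated one cytokines held (adjusted p = 0.0109) and the other 6 did not (adjusted p = 0.0954 to 0.29), and in block 2 alone the alveolar type 2 and ciliated lists were reversed (adjusted p = 0.397 and 0.304). Cxcl2, a neutrophil attractant, rose 5.32-fold (2.45 ± 1.78 against 0.45 ± 0.273 CPM, n = 9 and 10, adjusted p = 0.011, 9 of 9 libraries), Pdcd1 4.23-fold (10.6 ± 7.88 against 2.5 ± 0.993 CPM, adjusted p = 0.000583) and the EGF receptor ligand gene Areg 3.18-fold (57.4 ± 38.9 against 18 ± 8.97 CPM, adjusted p = 0.0266). The alveolar type 2 gene Lamp3 rose 2.27-fold (121 ± 78.4 against 53.1 ± 20.7 CPM, adjusted p = 0.0376). Among airway genes, Cckar of the club cell list fell 2.47-fold (81.8 ± 33.7 against 202 ± 82.9 CPM, adjusted p = 0.00985) and Sec14l3 of the ciliated list 1.85-fold (630 ± 229 against 1170 ± 309 CPM, adjusted p = 0.0181). In blocks 1 and 2 the log2 changes were 2.63 and 2.17 for Cxcl2, 1.78 and 2.25 for Pdcd1, 1.39 and 1.81 for Areg, 1.71 and 0.62 for Lamp3, −1.34 and −1.28 for Cckar and −1.21 and −0.35 for Sec14l3.

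The largest rises were in Glycam1 (5.43 ± 4.28 against 0.121 ± 0.259 CPM, adjusted p = 0.00104), the fibrinogen genes Fga (20.4-fold, adjusted p = 0.00107) and Fgg (10-fold, adjusted p = 0.0102, and 0.0808 without DKO NNK 7), the kininogen gene Kng2 (17.3-fold, adjusted p = 0.000692), the B cell receptor-like gene Fcrl5 (11.2-fold, adjusted p = 0.0116, and 0.106 without DKO NNK 4) and the cadherin gene Cdhr1 (10.2-fold, adjusted p = 0.00841). Outside on/off genes Nxpe4 fell 12.1-fold (1.27 ± 0.264 against 15.6 ± 6.75 CPM, adjusted p = 1.38e-07), and Lrp10 7.73-fold (adjusted p = 0.000142). Among on/off genes on chromosome 9, the cytochrome c oxidase subunit gene Cox7a2 (79755361 to 79759878) stood at 0.633 ± 0.353 against 165 ± 59.7 CPM and the fatty acid elongase gene Elovl5 (77917364 to 77984519) at 3.83 ± 2.76 against 335 ± 246 CPM (adjusted p = 9.52e-10 and 2.21e-07). Count ratios of baseline to NNK were 820 (147 to 32400) for Ifi213, 194 (66.2 to 944) for Cd244a, 197 (35 to 7810) for Paqr5 and 107 (29.3 to 888) for Sec22a, with adjusted p of 1.28e-06, 5.31e-06, 6.07e-07 and 2.88e-08.

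Cytokine and chemokine genes had a median of 1.15 (9 of 9 libraries, adjusted p = 3.48e-12, blocks 9.51e-06 and 8.93e-08, p = 0.0109 with estimated correlation). Of 17 genes 3 rose and 14 did not pass, 13 rose adjusted over the list alone. Cxcl1 rose 5.06-fold (adjusted p = 0.0135, 0.0647 without DKO NNK 6, and log2 1.22 in block 1) and Il10 7.04-fold (adjusted p = 0.0369). P53 targets had a median of 0.26 (9 of 9 libraries, adjusted p = 0.000572, blocks 0.0264 and 0.000421, p = 0.0109 with estimated correlation). Of 21 genes 1 rose and 20 did not pass, 3 rose adjusted over the list alone, with Psrc1 2.64-fold higher (adjusted p = 0.0034). These were the 2 lists of any comparison that held with an estimated correlation. Immune checkpoint genes had a median of 0.78 (9 of 9 libraries, adjusted p = 3.01e-07, blocks 0.00294 and 1.09e-05, p = 0.0954 with estimated correlation). Of 14 genes 1 rose and 13 did not pass, 9 rose and 1 fell adjusted over the list alone. MAPK output genes had a median of 0.59 (9 of 9 libraries, adjusted p = 3.92e-06, blocks 0.000218 and 0.00344, p = 0.0954 with estimated correlation). Of 15 genes 2 rose and 13 did not pass, 6 rose and 1 fell adjusted over the list alone, and the ETS factor gene Etv4 rose 5.67-fold (adjusted p = 0.0112, log2 1.42 in block 2). Alveolar type 2 markers had a median of 0.61 (7 of 9 libraries, adjusted p = 4.35e-05, blocks 1.98e-06 and 0.397 reversed, p = 0.29 with estimated correlation). Of 14 genes 2 rose and 12 did not pass, 7 rose adjusted over the list alone, with Chil1 2.06-fold higher (adjusted p = 0.0294). MHC class II genes had a median of 0.49 (8 of 9 libraries, adjusted p = 0.000692, blocks 0.00398 and 0.053, p = 0.29 with estimated correlation). Of 12 genes 1 rose and 11 did not pass, 1 rose adjusted over the list alone, with H2-DMb1 1.85-fold higher (adjusted p = 0.0175, and 0.0715 without DKO NNK 2).

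Interstitial macrophage and monocyte markers had a median of 0.22 (7 of 9 libraries, adjusted p = 0.00397, blocks 0.187 and 0.00805, p = 0.121 with estimated correlation). Of 13 genes 3 rose and 10 did not pass, 4 rose adjusted over the list alone. Ms4a7 rose 3.06-fold and C1qb 2.04-fold (adjusted p = 0.00356 and 0.0259). Alveolar macrophage markers had a median of 0.07 (6 of 9 libraries, adjusted p = 0.00301, blocks 0.00501 and 0.358, p = 0.302 with estimated correlation). Of 14 genes 1 rose and 13 did not pass, 4 rose adjusted over the list alone, with Mrc1 1.8-fold higher (adjusted p = 0.00144). Neutrophil markers had a median of 0.68 (8 of 9 libraries, adjusted p = 0.00335, blocks 0.058 and 0.00441, p = 0.481 with estimated correlation). Of 15 genes 1 rose and 14 did not pass, 1 rose adjusted over the list alone, with Hdc, the histamine-forming enzyme, 2.4-fold higher (adjusted p = 0.0259). Plasma cell markers had a median of 0.56 (8 of 9 libraries, adjusted p = 0.00151, blocks 0.057 and 0.0018, p = 0.172 with estimated correlation). Of 12 genes 0 passed in edgeR (4 higher at unadjusted p under 0.05), 2 rose adjusted over the list alone. T cell markers had a median of 0.28 (7 of 9 libraries, adjusted p = 0.035, blocks 0.854 and 0.00251, p = 0.63 with estimated correlation). Of 18 genes 0 passed in edgeR (4 higher at unadjusted p under 0.05), 4 rose adjusted over the list alone. NK and cytotoxic cell markers had a median of −0.54 (8 of 9 libraries, adjusted p = 0.0276, blocks 0.0588 and 0.231, p = 0.601 with estimated correlation). Of 11 genes 1 fell and 10 did not pass, 1 rose and 3 fell adjusted over the list alone, with the granzyme gene Gzma 3.51-fold lower (adjusted p = 0.0406).

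Ciliated cell markers had a median of −0.49 (6 of 9 libraries, adjusted p = 3.87e-08, blocks 1.18e-10 and 0.304 reversed, p = 0.29 with estimated correlation). Of 17 genes 1 fell and 16 did not pass, 1 fell adjusted over the list alone. Club cell markers had a median of −0.79 (7 of 9 libraries, adjusted p = 4.23e-05, blocks 1.14e-06 and 0.26, p = 0.121 with estimated correlation). Of 13 genes 1 fell and 12 did not pass, 6 fell adjusted over the list alone. Smooth muscle and pericyte markers had a median of −0.31 (9 of 9 libraries, adjusted p = 0.00145, blocks 0.000342 and 0.304, p = 0.29 with estimated correlation). Of 10 genes 1 fell and 9 did not pass, 1 fell adjusted over the list alone, with Notch3 1.87-fold lower (adjusted p = 0.00615). Matrix genes had a median of −0.30 (8 of 9 libraries, adjusted p = 0.00151, blocks 0.00402 and 0.0725, p = 0.481 with estimated correlation). Of 26 genes 1 rose, 4 fell and 21 did not pass, 2 rose and 6 fell adjusted over the list alone. Fbn1 fell 1.96-fold, Mmp2 2.04-fold and Col1a1 2.17-fold (adjusted p = 0.00158, 0.00478 and 0.00516), and Mmp12, named after its values were seen, rose (log2 1.99, adjusted p = 0.0396). Endothelial markers had a median of −0.25 (9 of 9 libraries, adjusted p = 0.0456, blocks 0.336 and 0.00433, p = 0.601 with estimated correlation). Of 15 genes 1 fell and 14 did not pass, 1 fell adjusted over the list alone, with Kdr 1.78-fold lower (adjusted p = 0.00356).

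Xenobiotic enzymes had a median of −0.16 (6 of 9 libraries, adjusted p = 0.0456, blocks 0.000343 and 0.133 reversed, p = 0.601 with estimated correlation). Of 28 genes 1 rose, 1 fell and 26 did not pass, 3 rose and 6 fell adjusted over the list alone, with Gstm2 1.81-fold lower (adjusted p = 0.0488, log2 −0.36 in block 2) and Akr1b8, named after its values were seen, higher (log2 1.32, adjusted p = 0.000213). Acute phase and epithelial defence genes had a median of 0.40 (5 of 9 libraries, adjusted p = 0.0456, blocks 0.906 and 0.00137, p = 0.481 with estimated correlation). Of 20 genes 1 rose and 19 did not pass, 4 rose adjusted over the list alone. Immediate early genes had a median of 0.31 (7 of 9 libraries, adjusted p = 0.00909, blocks 0.495 and 0.000399, p = 0.519 with estimated correlation). Of 20 genes 0 passed in edgeR (6 higher at unadjusted p under 0.05), 2 rose adjusted over the list alone. Skeletal muscle genes, 5 of them on/off, had a median of 0.85 (7 of 9 libraries, adjusted p = 0.0456, blocks 0.057 and 0.397, p = 0.628 with estimated correlation). DKO NNK 6 stood apart at −4.22 (others −0.29 to 2.04). Of 7 genes 0 passed in edgeR (0 at unadjusted p under 0.05), 0 passed adjusted over the list alone. The lung tumour list (adjusted p = 0.0725) and the interferon response list (adjusted p = 0.102) were not past the threshold. In all 262 genes passed, 137 higher and 125 lower, and 1925 had an unadjusted p under 0.05. Limma-trend on log2(TPM + 1) called 247, with 157 higher and 90 lower, and edgeR without a filter 224, with 140 and 84. Of the 262, 23 were on/off genes and 260 had the same sign in both blocks. The model with letter and block called 958 (495 higher, 463 lower), block 1 alone 504 and block 2 alone 453. With that model the lists of skeletal muscle, acute phase, xenobiotic and T cell genes had adjusted p of 0.0526, 0.0592, 0.085 and 0.0518. KO and DKO lungs shared 45 genes higher after NNK, where independent lists would share 3.95, and 38 lower, where they would share 3.47.

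**Figure D4:**
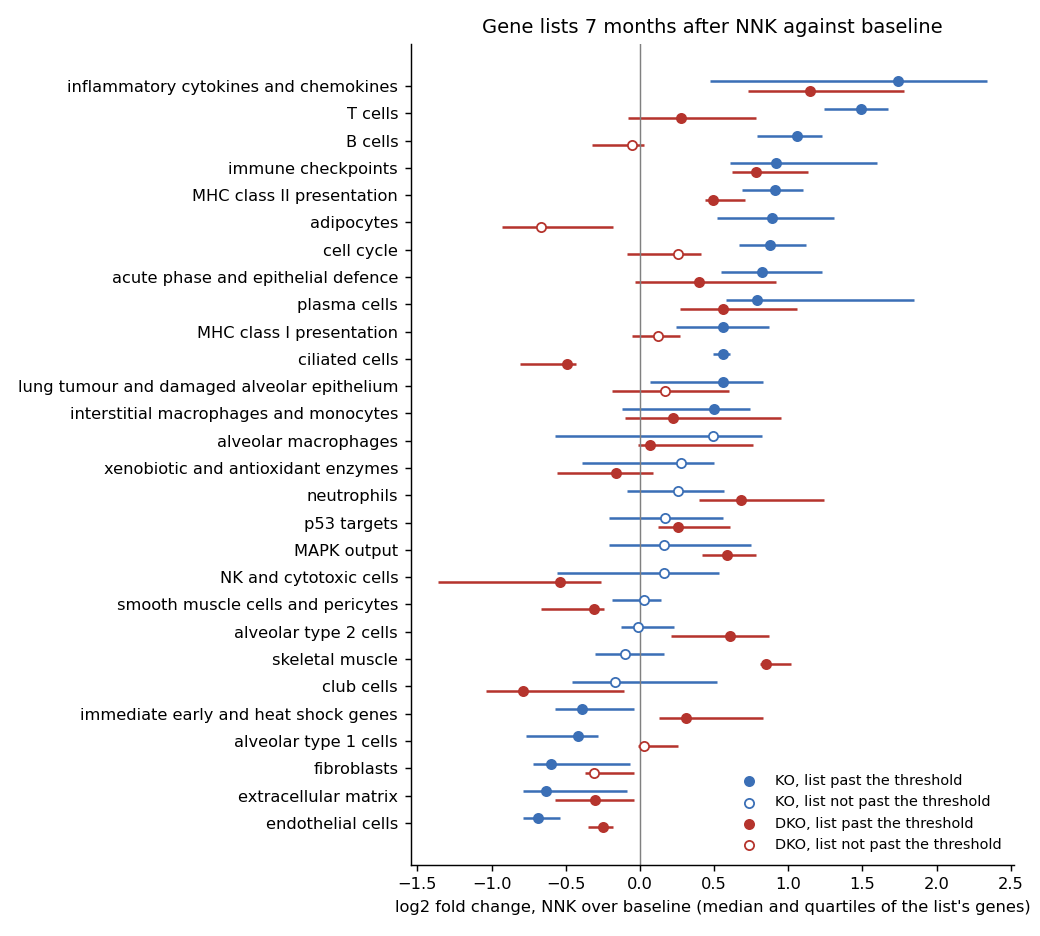
Log2 change from baseline to NNK of the gene lists past the threshold in KO or DKO lungs. Points are the medians and bars the quartiles of a list's genes, and filled points passed the list test; cytokines and chemokines lie at 1.74 in KO and 1.15 in DKO lungs, and endothelial markers at −0.69 and −0.25.

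The interaction asked whether the change after NNK differed between the genotypes; positive values mean a larger rise or a smaller fall in DKO lungs. The replication helicase gene Mcm6 stood at 8.66 ± 1.84 CPM at baseline and 17.6 ± 6.07 after NNK in KO lungs, against 13.4 ± 3.64 and 11.1 ± 3.1 in DKO lungs (interaction log2 −1.30 ± 0.293 SE, adjusted p = 0.0218, −1.39 and −1.16 in the blocks). Ctse stood at 24.7 ± 11.8 CPM at baseline and 5.38 ± 4.31 after NNK in KO lungs, against 2.12 ± 1.14 and 3.04 ± 2.86 in DKO lungs (log2 2.71 ± 0.644, adjusted p = 0.0333, 2.10 and 3.29 in the blocks). Aoc1, a diamine oxidase gene, stood at 4.57 ± 3.4 CPM at baseline and 36.8 ± 29 after NNK in KO lungs, against 5.84 ± 2.18 and 7.72 ± 3.66 in DKO lungs (log2 −2.59 ± 0.549, adjusted p = 0.0109, −3.11 and −1.02 in the blocks). Among on/off genes the interaction log2 values were 8.99 (adjusted p = 9.33e-16) for Naip6 and 7.72 (adjusted p = 2.58e-07) for Phlda3. Rrm2, at 0 in KO baseline lungs, and Ifi213, at 0.0219 CPM in DKO NNK lungs, also passed (adjusted p = 0.000316 and 3.83e-05), but their fitted values depend on the prior count.

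Of the lists, 15 passed at the preset correlation; the median log2 of each comes first. Ciliated cell genes were lower in the interaction (−1.04, adjusted p = 5.43e-13, blocks 4.05e-19 and 0.239 reversed), and 14 of 17 passed adjusted over the list alone. Cell cycle genes were lower (−0.69, adjusted p = 8.31e-05, blocks 0.00415 and 0.0229): 2 of 25 passed over all genes, Rrm2 and Mcm6, 23 did not, and 3 passed adjusted over the list alone. Also lower were interferon response (−0.52, adjusted p = 0.00476, blocks 0.0383 and 0.102), xenobiotic (−0.30, adjusted p = 0.0044, blocks 0.00011 and 0.806 reversed) and acute phase genes (−0.39, adjusted p = 0.0443, blocks 0.000592 and 0.872 reversed). Higher were immediate early genes (0.90, adjusted p = 0.000209, blocks 0.0139 and 0.00768), alveolar type 2 (0.58, adjusted p = 0.000272, blocks 0.00037 and 0.121), alveolar type 1 (0.56, adjusted p = 0.00415, blocks 0.00194 and 0.0229), endothelial (0.41, adjusted p = 0.00415, blocks 0.017 and 0.0105) and mesothelial markers (0.76, adjusted p = 0.0379, blocks 0.181 and 0.208), and MAPK output genes (0.26, adjusted p = 0.00835, blocks 0.0109 and 0.259). Each of these 11 had an adjusted p = 0.538 with estimated correlation. B cell (−1.13, adjusted p = 0.00549, blocks 0.642 and 5.75e-05, p = 0.579 with estimated correlation), MHC class I (−0.41, adjusted p = 0.044, blocks 0.306 and 0.0425, p = 0.573 with estimated correlation) and smooth muscle genes (−0.29, adjusted p = 0.0398, blocks 0.0113 and 0.818, p = 0.573 with estimated correlation) were lower and neutrophil markers (0.58, adjusted p = 0.0232, blocks 0.00177 and 0.734, p = 0.579 with estimated correlation) higher.

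Outside the cell cycle list 0 members passed over all genes tested (edgeR), while 14 ciliated, 7 B cell, 7 immediate early, 4 interferon, 4 alveolar type 2, 4 xenobiotic, 3 MAPK, 2 MHC class I, 2 alveolar type 1, 2 endothelial, 2 mesothelial, 0 smooth muscle, 0 neutrophil and 0 acute phase genes had an unadjusted p under 0.05 in the list's direction. Adjusted over the list alone, 2 immediate early, 2 endothelial, 2 interferon, 1 mesothelial and 1 xenobiotic gene passed, and 0 in the other 8. With letter and block in the model the mesothelial and MHC class I lists had adjusted p of 0.0503 and 0.0617. In all 79 genes passed, 32 higher and 47 lower, and 1586 had an unadjusted p under 0.05. Limma-trend on log2(TPM + 1) called 69, with 50 higher and 19 lower, and limma-voom 43, with 22 and 21. Of the 79, 29 were on/off genes and 77 had the same sign in both blocks. The model with letter and block called 480 (198 higher, 282 lower), block 1 alone 235 (41 and 194) and block 2 alone 188 (119 and 69).

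**Figure D5:**
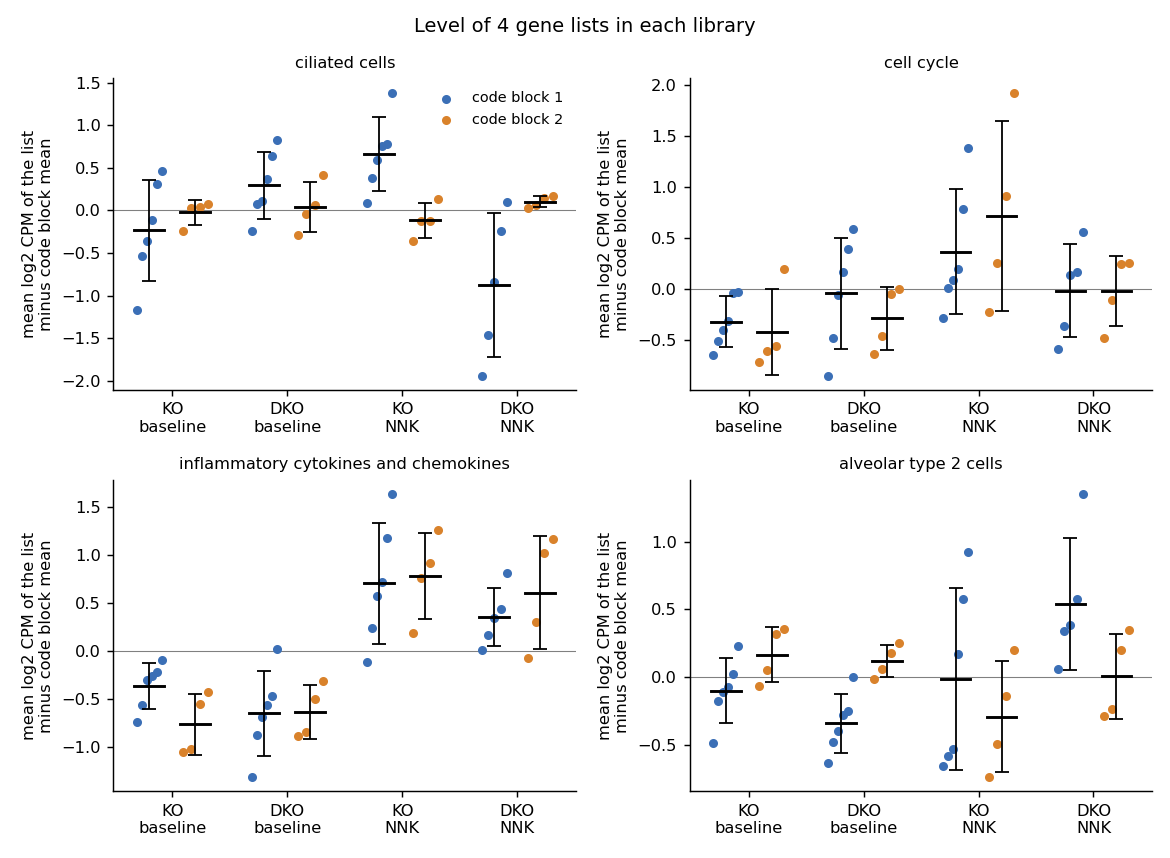
Level of the ciliated, cell cycle, cytokine and alveolar type 2 lists, as the mean log2 CPM of the members less the mean of the code block, by group and block. Points are libraries and black lines the mean and SD within a block; after NNK the ciliated level of DKO less that of KO libraries was −1.54 in block 1 and 0.22 in block 2.

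The other 12 lists passed in no comparison, with adjusted p at the preset correlation, lowest to highest over the 5 comparisons, of 0.0672 to 0.999 for mast cells and basophils, 0.103 to 0.704 for erythroid cells, 0.124 to 0.738 for basal and squamous cells, 0.13 to 0.972 for surfactant lipid synthesis and 0.163 to 0.972 for cardiac muscle. The ranges were 0.182 to 0.818 for TGF-beta and Wnt targets, 0.263 to 0.632 for the chromosome 2 neighbours of Lcn2, 0.265 to 0.985 for oxidative phosphorylation and 0.282 to 0.912 for ribosomal proteins. They were 0.285 to 0.929 for iron handling, 0.44 to 0.912 for the circadian clock and 0.451 to 0.952 for dendritic cells.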

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

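The tests for a swapped label and a genotype effect on the ciliated list, and the repeats named below, were chosen only after the results were seen. In groups of 9 or 10, the highest or lowest library was singled out by Dixon's test (gap to the next past its 95% limit). Chance passes this in about 1 in 20 groups, but with all others at 0, shown as (0), any count passes. This was so for 39 of 397 gene and group combinations, 7 of 106 for lists and 0 of 8 library measures. Values are CPM or log2 list levels, with the nearest other in parentheses. KO NNK 1 had 1020 for Cd24a (591), 85.7 for Gp2 (11), −2.96 for the MHC class II list (−0.19) and 2.13 for the acute phase list (0.83). DKO baseline 8 had 0.489 for Cdhr1 (0.169), 0.652 for Eml6 (2.44), 0.815 for Glycam1 (0.253) and 0.326 for Hist1h4m (0.142). KO baseline 4 had 1.22 for Pdcd1 (2.14), 16.1 for Riok2 (0.571), 1.01 for the mesothelial cells list (0.28) and 0.61 for the plasma cells list (−0.08). DKO NNK 4 had 186 for C1qb (74.3), 59.7 for Kdr (93.6) and 0.118 for Tmem181a (0). DKO NNK 7 had 0.394 for Cd244a (0.118), 0.197 for Ifi213 (0) and 0.197 for Paqr5 (0). KO baseline 1 had 9.31 for Ctla4 (4.56), 0.763 for Glycam1 (0.308) and 1.22 for Nxpe4 (9.12). KO NNK 4 had 4.95 for Cyp26b1 (10.9), 28 for Fbln1 (56) and −1.33 for the fibroblasts list (−0.61). DKO baseline 5 had 0.619 for Elk3 (46.9), 1.36 for Lta4h (38.5) and 0 for Vezt (2.28). KO NNK 6 had 179 for Alb (8.59) and 53.8 for Apoa2 (2.41). DKO NNK 6 had 957 for Dusp1 (367) and −4.22 for the skeletal muscle list (−0.29). Single values were 2.41 for Atpaf2 in KO NNK 3 (0.382), 0.714 for Cdhr1 in KO baseline 8 (0.299), 0.169 for Cntnap2 in DKO baseline 9 (0), 54.2 for Lrp10 in KO NNK 5 (86) and 4.17 for Mcm6 in DKO baseline 6 (11.4). Further values were 0.621 for Myh2 in DKO baseline 3 (0.169), 0.445 for Naip6 in KO NNK 7 (0.126), 1.17 for Nxpe4 in KO NNK 2 (4.7), 0.252 for Phlda3 in DKO NNK 3 (23.8) and 14.2 for Psrc1 in DKO baseline 4 (6.26). Others were 0.126 for Raet1e in DKO baseline 7 (0), 0 for Sec22a in DKO baseline 1 (1.69), 0.747 for Sectm1b in KO baseline 5 (0.308), 0.146 for Sycp1 in DKO baseline 10 (0) and 0.88 for the acute phase list in KO baseline 3 (−0.11).

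The interaction (edgeR) set apart 31 named genes whose change after NNK differed between DKO and KO lungs. The log2 differences, DKO minus KO, were 8.99 for Naip6, 7.72 for Phlda3, 7.67 for Ephb1, 6.45 for Tfcp2l1, 6.04 for Nek11, 5.69 for Acy1, 5.67 for Hist1h4m and 4.78 for Als2cl. They were 2.71 for Ctse, 2.66 for Lyrm7, 2.20 for Klhdc8b, 1.76 for Sertad1, 1.71 for Eml6, 1.69 for Colgalt2 and 1.52 for Prmt8. Negative differences were −9.48 for Rrm2, −8.53 for Ifi213, −7.06 for Cd244a, −7.06 for Cilp, −6.75 for Paqr5, −6.40 for Sec22a, −6.10 for Ifi206 and −6.09 for Igsf8. They reached −4.93 for Herc6, −4.53 for Rd3, −3.20 for Lrp10, −2.86 for Nxpe4, −2.86 for Adgra3, −2.62 for Ptprv, −2.59 for Aoc1 and −1.30 for Mcm6. Fitted values of Rrm2, Ephb1, Cilp and other genes with few or no counts in a group depend on the prior count. Camera set apart 15 lists, with adjusted p of 0.000272 for alveolar type 2 cells, 0.00415 for alveolar type 1 cells, 5.43e-13 for ciliated cells, 0.0232 for neutrophils, 0.00549 for B cells, 0.00415 for endothelial cells, 0.0398 for smooth muscle and 0.0379 for mesothelial cells. The others had 0.0443 for acute phase, 0.00476 for interferon response, 0.044 for MHC class I presentation, 8.31e-05 for cell cycle, 0.00835 for MAPK output, 0.0044 for xenobiotic enzymes and 0.000209 for immediate early genes; with an estimated correlation the adjusted p was 0.538 to 0.579.

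Of the 175 on/off genes 50, among them the squamous and muscle genes above, share the 3 low libraries of block 2 named there. A response to NNK or age alone is argued against by 31 of the 54 on/off genes called between NNK and baseline, for which baseline libraries of 1 genotype and block lie on both sides. Pairs of on/off genes within 5 Mb had a median absolute correlation of their states of 1 (148 pairs), against 0.22 for unlinked pairs (highest of 10000 draws 0.33). In the repeat without the 50 it was 1 over 69 pairs, against 0 (highest draw 0.22). Over its 25 clusters of neighbours the median was 0.77, with 12 at 0.9 or more. For genes outside the 50 a candidate explanation is inherited variants of a mixed strain background, under a primer or acting on expression. Strain and genotype data were not analysed here.

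KO NNK 7, whose title opens with F, had 390 CPM of Xist (other F libraries of its block 716 to 1080, M libraries up to 4.73) and, of the Y genes Ddx3y, Uty, Eif2s3y and Kdm5d, 46.8%, 42.5%, 32.7% and 18.2% of the M mean. A swapped label is argued against by Xist at 82.6 times the highest M library. For reads of another library mixed in, the test set beforehand counted genes with a gap between 2 levels in which this library lay in the middle, 2 against up to 16 in another library, which met the bound set against a mixture, and a version on linear CPM added afterwards gave 11 against up to 66. Mixtures of 2 libraries then made at a share of 37.6% gave 0 to 59 such genes (median 5), 50 of 56 no more than 16 and 11 of 56 no more than this library's 2, so that bound was wrong and a mixture stays open. No biological explanation was tested.

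After NNK the ciliated list level of DKO minus KO lungs was −1.54 in block 1 (exact permutation p = 0.00433, n = 5 and 6), 0.22 in block 2 (exact permutation p = 0.0857, n = 4 and 4) and −0.79 pooled (exact permutation p = 0.0147). Markers of club cells, also of the conducting airway, differed by −1.32, 0.3 and −0.63 (exact permutation p = 0.0368, 0.229 and 0.105). The levels of both lists correlated across libraries in block 1 with r = 0.66 (n = 23, permutation p = 0.00272, adjusted over 6 correlations 0.0163; rho = 0.64, p = 0.00299, adjusted 0.0179; r = 0.58 without the 2 libraries farthest from the median). In block 2 they gave r = 0.47 (n = 16, permutation p = 0.102, adjusted 0.204; rho = 0.39, p = 0.171, adjusted 0.342) and 0.07 without the 2 farthest, on which the relation rests. A differing share of conducting airway in the lung piece (r of 0.47 in block 2, between the bounds of 0.2 and 0.5 set beforehand) and an effect of the Lcn2 genotype after NNK (0.22 there, of opposite sign to block 1 but not past the threshold, while camera at its preset correlation gave an adjusted p of 0.0458) cannot be told apart here, as neither value decides.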

How the results depend on the processing

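The fits within 1 code block and without on/off genes were added after the data were seen; the other settings were set beforehand. No paired analysis was possible because no label pairs mice across groups. Counts of genes, 79, 264, 839, 262 and 79 for the genotype at baseline, the genotype after NNK, NNK in KO, NNK in DKO and the interaction, moved by more than 1.5 times under some settings, given in that order where all 5 did. DESeq2 gave 121 for the genotype at baseline, 486 for the genotype after NNK, 503 for NNK in DKO and 208 for the interaction. The block as a term gave 165, 1152, 1971, 866 and 431. Letter and block gave 181, 1355, 2106, 958 and 480. Surrogate variables gave 198, 2501, 2678, 1583 and 940. Only the groups compared gave 138 for the genotype after NNK and 464 for NNK in KO. Block 1 alone gave 603 for the genotype after NNK, 504 for NNK in DKO and 235 for the interaction. Block 2 alone gave 526, 453 and 188 for these and 2968 for NNK in KO. Limma-voom gave 163 for NNK in DKO and 43 for the interaction. Without on/off genes the interaction had 50. Counts of lists were 5, 11, 18, 21 and 15 in that order. They became 0, 0, 0, 2 and 0 with an estimated correlation. With fry they were 0, 2, 12, 7 and 0, and in block 2 alone 3, 7, 16, 16 and 6. At an unadjusted p under 0.05 the estimated correlation called 1, 6, 8, 7 and 1, and fry 1 at baseline and 3 in the interaction. Fry asks another question than camera, and the block term also called more simulated changes. Elsewhere the cause was not tested.

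Without any 1 library the counts ran over 63 to 84, 179 to 314, 571 to 890, 172 to 295 and 62 to 117 genes and 3 to 6, 10 to 15, 17 to 21, 16 to 22 and 12 to 18 lists. The count for NNK in DKO was 174 without DKO NNK 2, 174 without DKO baseline 3 and 172 without DKO NNK 7, and lists at baseline were 3 without KO baseline 10. Without KO NNK 7 there were 78, 270, 777, 246 and 91 genes and 5, 12, 18, 21 and 16 lists. Of the 70 list results 51, and of 209 named gene results 165, kept their call without any 1 library; calls ended by leaving out 1 library stand beside the genes named, and those ended by any of 2 or 3 were Chil1 with NNK in KO (KO NNK 1 or 4, adjusted p 0.0655 and 0.0796), Hdc (DKO NNK 1, 2 or 3, 0.0559 to 0.0714), C1qb (DKO NNK 4 or 7 or DKO baseline 5, 0.0506 to 0.104) and immediate early genes (DKO NNK 5 or 6, 0.0511 to 0.097) with NNK in DKO, and neutrophils at baseline (DKO baseline 6 or KO baseline 5 or 10, 0.0527 to 0.0891). Other calls ended without any 1 of 5 to 31 libraries: Akap5, Ctss, Dusp1, Fbln1, Psmb9, Spock2 and Trem2 with NNK in KO, Areg, Chil1, Gstm2 (31, adjusted p 0.0502 to 0.106), Gzma, Il10 and Lamp3 with NNK in DKO, Aurka, Dnah5, Dusp1 and Pou2af1 with the genotype after NNK, Ctse, Eml6 and Sertad1 in the interaction, 6 genes not described and 15 list results.

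Direction turned in block 2 alone for Muc4 with NNK in KO (log2 −0.17, adjusted p = 0.732) and for 8 list results, given as −log10 p with the sign of the direction: ciliated cells with the genotype after NNK (2.12, adjusted p = 0.0458), NNK in KO (−0.42), NNK in DKO (0.65) and the interaction (1.04), alveolar type 2 cells (−0.48) and xenobiotic enzymes (1.22) with NNK in DKO, and acute phase (0.09) and xenobiotic genes (0.15) in the interaction; the cause was not tested. The other results kept their direction. Of 70 list results the calls held for 68 with DESeq2 size factors, 68 with a prior count of 0.5, 64 with letter and block, 49 in block 1, 35 in block 2, 20 with fry and 2 with an estimated correlation. Of 209 named gene results they held for 208 with DESeq2 size factors, 208 with its Wald test, 209 with letter and block, 207 with the letter, 208 with surrogate variables, 203 with no filter, 149 on log2(TPM + 1), 116 with limma-voom, 158 in block 1 and 152 in block 2, and for 112 of 129 with only the groups compared. A 1.5-fold change was called in 2% to 18% of simulated genes by group alone and 4% to 34% with the block as a term, so such changes were mostly not detectable.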

Other observations

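The genes of this paragraph and the next were chosen after their values were seen, and counts of libraries are of those beyond the median of the group compared with, with log2 values in blocks 1 and 2. Cyp2a5, a cytochrome P450 gene whose enzyme metabolises nicotine and NNK, stood at 30 ± 23.7 CPM (SD, n = 10) in KO baseline and 318 ± 215 CPM (n = 10) in KO NNK lungs (log2 3.41, adjusted p = 7.26e-05, 10 of 10 libraries, blocks 3.48 and 2.83). In DKO NNK lungs it stood at 44.2 ± 36.8 CPM (n = 9), lower than in KO NNK lungs (log2 −2.85, adjusted p = 0.0016, 9 of 9 libraries, blocks −3.06 and −1.66), although the interaction did not pass (adjusted p = 0.313). Pglyrp1, which encodes a bactericidal protein of neutrophil granules, rose in KO lungs (log2 1.62, adjusted p = 0.000533, 10 of 10 libraries, blocks 1.59 and 1.64) and was lower in DKO than in KO NNK lungs (20.4 ± 11 CPM (n = 9) against 87.5 ± 56.9 (n = 10); log2 −2.10, adjusted p = 2.57e-05, 9 of 9 libraries, blocks −2.73 and −1.08), with an interaction adjusted p of 0.159.

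Il4ra, the receptor gene of interleukins 4 and 13, was higher in DKO than in KO NNK lungs (167 ± 42.1 CPM (n = 9) against 56.1 ± 32.4 (n = 10); log2 1.58, adjusted p = 0.000515, 9 of 9 libraries, blocks 1.34 and 1.86). Prg2, which encodes the major basic protein of eosinophils, rose from 0.781 ± 0.99 (n = 10) to 11.3 ± 5.95 CPM (n = 10) in KO lungs (log2 3.78, adjusted p = 4.43e-05, 10 of 10 libraries, blocks 3.33 and 4.75) and from 0.582 ± 0.458 (n = 10) to 3.23 ± 1.57 CPM (n = 9) in DKO lungs (log2 2.43, adjusted p = 0.0159, 9 of 9 libraries, blocks 1.87 and 3.01). These differences with NNK are also differences of age.

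Other splits of the libraries compared into groups of the same sizes, 100 with the real one and set beforehand, tested whether chance gives as many calls. Only the real split called as many (1 of 100, the smallest share possible) for genes by genotype at baseline (79 against at most 12). The same holds by genotype after NNK (264 against 29) and for NNK in DKO (262 against 94), so chance is unlikely but not excluded. Chance stays open for NNK in KO (2 of 100, 839 against 1753) and the interaction (3 of 100, 79 against 2928). The split with 1753 genes put 6 more block 1 libraries on one side, but 2 others uneven by 6 called 0 (edgeR). For the interaction (2928 and 349 genes) balance was measured in only some of the groups and cannot decide. Counts several times the real one point to a structure of the samples, and its source was not tested. With the block as a term and splits inside the blocks, chance is likewise unlikely but not excluded (1 of 100 each). Counts were 165 against at most 133, 1152 against 129, 1971 against 1649, 866 against 354 and 431 against 15. For the number of lists chance stays open with NNK in DKO (3 of 100, 21 against 22). So it does by genotype at baseline (69, 5 against 21) and after NNK (60, 11 against 24). It also does with NNK in KO (7, 18 against 21) and the interaction (21, 15 against 23).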
